A study of Homo sapiens with 4 samples.

How the data were processed

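The data are RNA-seq gene counts of 4 libraries from SK-N-BE(2) cells, 2 with a control shRNA and 2 with an shRNA against CDK5RAP3. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with an Illumina TruSeq RNA kit, and per the series' design text the libraries were read on a NovaSeq instrument. The authors deposited 1 table of whole-number counts per Ensembl gene identifier, not scaled between libraries. Per the submitters' processing notes, HISAT2 2.2.0, StringTie and the genome build hg38 were used, with no roles or order given. The annotation release, the strand setting, the treatment of reads that map to several places, and the number and sequences of the hairpins are not given in the sources used here.

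Groups and replicate numbers came from the sample titles, and all 4 count columns were matched to samples by the descriptions in the labels. The table has 64252 rows, of which 30331 are 0 in every library. Identifiers were matched to GENCODE 29 (GRCh38) and a table of gene names: 56591 matched and 7661 did not, and the latter held 1.82% to 1.90% of the counts of a library. They stayed in library sizes and tests. Total counts were 28721740 and 28755837 in the shControl libraries and 28653689 and 30138393 in the shCDK5RAP3 libraries. At this depth a gene with a count of 0 in a library allows up to 3 counts, about 0.103 CPM, a floor that covers counting error only.

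All tests were run in R 4.3.3. The main comparison used edgeR 4.0.16 with TMM factors, its default filter by group (18775 genes kept), estimateDisp, and the quasi-likelihood fit and test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. It had no replicate block, since nothing in the labels says that equal numbers share a culture or day. Log2 fold changes are shCDK5RAP3 over shControl, standard errors are the log2 fold change divided by the square root of the quasi-likelihood F statistic, and CPM values use TMM-scaled library sizes. The biological coefficient of variation was 0.0959.

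Before the data were examined, 30 gene lists were fixed: UFMylation, ER-phagy receptors, autophagy, lysosome, ER chaperones, cell-state and lineage lists, other cell types, cell cycle, stress, metabolism, ribosome and RNA-quality lists. Lists with at least 5 tested members, 28 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Counts adjusted over the list alone repeat the Benjamini-Hochberg step within a list. None of the 9 lists that passed did so with an estimated correlation, where the lowest adjusted p was 0.517. With only 4 libraries that version of camera has few degrees of freedom, so it cannot decide whether correlation between genes made these calls. The directional test of fry, which asks whether a list moves 1 way without comparing it with other genes, called 20 lists.

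Named genes followed a rule fixed at the same time. They are CDK5RAP3, all tested members of 3 lists (UFMylation, ER-phagy receptors, adrenergic circuit), the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and groups that do not overlap, and up to 4 members of each other list with the largest change. Some genes that the rule picks are not reported here. Where several rows carry 1 symbol, the row with the higher mean count was used. Genes that overlap, have near-identical copies or lie antisense to another gene are reported as uncertain.

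The alternatives fixed in advance were other scaling factors, no filter or a stricter one (CPM of at least 1 in 2 libraries), DESeq2 1.42.0, a robust fit, limma-trend, a replicate block, rows summed by symbol, a threshold of 0.01, and each library left out in turn. A correction for GC content and length, the restriction to annotated genes, and the removal of genes with certain 3′ UTR words were added after seeing the data. For the 3′ UTR words, the longest annotated 3′ UTR of each protein-coding gene with a log2 CPM of at least 1 was taken from GENCODE 29, and every 7-base word was tested against the fold change after regression on UTR length and base composition, with 100 permutations of the residuals.

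The analysis was run on simulated data. With counts drawn for 18775 genes at the depths of this comparison and 50 genes at each planted change, edgeR recovered 50 of 50 at a log2 change of -2, 46 at -1, 50 at 1 and 22 at 0.5, and called 6 of 18545 unchanged genes. Every simulated gene had the same dispersion, and changes were planted only in genes with a CPM of at least 1. In the real comparison the spread differs by gene and 7792 genes passed, so these rates may not hold there. A list of 30 genes shifted by 0.4 was called with an estimated correlation too (camera adjusted p = 0.0165, over this and an unshifted list only). Its genes were drawn independently of each other, so this does not show that the test could call a list of correlated genes here. With the preset correlation the same list had a camera adjusted p of 1.21e-21. The p-value thus rose greatly without correlated genes, so a call lost with an estimated correlation need not come from correlation.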

Results

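Gene expression was measured by RNA sequencing in SK-N-BE(2) cells, a human neuroblastoma line with an amplified MYCN gene and a noradrenergic character. The cells carried either a control short hairpin RNA (shControl) or a hairpin against CDK5RAP3 (shCDK5RAP3), a protein that binds the UFM1 ligase UFL1 at the endoplasmic reticulum (ER). Each group had 2 libraries. Total counts were 28721740 and 28755837 in the shControl libraries and 28653689 and 30138393 in the shCDK5RAP3 libraries, so depth differed little between groups. Libraries of 1 group differed from each other by more than counting noise, with a chi-square of 10.4 per degree of freedom between the shControl libraries and 7.95 between the shCDK5RAP3 libraries over 14287 genes, against 98.2 to 112 between libraries of different groups. Nothing in the labels says that the replicates were separate cultures, so every p-value measures only the spread between these libraries. The study's title places CDK5RAP3 between the master transcription factors of neuroblastoma and ER-phagy, the degradation of ER by autophagy. The single comparison asks which transcripts differed once CDK5RAP3 mRNA was lowered.

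CDK5RAP3 mRNA (ENSG00000108465, GRCh38 chromosome 17, 47967810 to 47981774) fell to 62.1% of its control level. It had 2529 and 2866 counts in the shControl libraries and 1669 and 1689 in the shCDK5RAP3 libraries. Scaled by library size (CPM) this was 93.0 ± 7.90 (SD, n = 2) against 57.8 ± 0.966 (SD, n = 2), a log2 fold change of -0.69 with a standard error of 0.08 (edgeR adjusted p = 0.000163). Both shCDK5RAP3 libraries lay below both shControl libraries.

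Beside this partial loss, expression changed widely. Of 35 genes of noradrenergic neuron function 24 fell, among them the chromogranins CHGA and CHGB (list adjusted p = 0.517 with an estimated correlation), and so did MYCN, LMO1 and other regulators of the noradrenergic state. Of the heat-shock genes 18 of 20 rose, of the immediate-early genes 17 of 24, of the NRF2 targets 12 of 24 and of the ribosomal proteins 50 of 79. With an estimated correlation none of these 4 lists passed the camera test (adjusted p = 0.517 for the first 3 and 0.651 for the ribosomal proteins). Among ER-phagy receptors RTN3 fell most, to 37.7% of control, while most transcripts of the UFMylation enzymes themselves did not pass.

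Of 18775 genes tested, 7792 passed an edgeR adjusted p of 0.05, of which 3704 were higher and 4088 lower in the shCDK5RAP3 libraries. Among them 1972 changed at least 2-fold, 604 upward and 1368 downward, and the median absolute log2 change of the genes that passed was 0.61. The groups did not overlap for 13404 of the tested genes, or 71.4%, where chance gives 33.3%. The count of genes that passed falls to 4836 without shCDK5RAP3 replicate 1 and to 3752 without shCDK5RAP3 replicate 2, where the lone library left in that group is assumed to vary like the control libraries. Without a filter on low counts 4488 genes passed, and 30 of the genes picked by the naming rule lost their calls.

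**Figure D1:**
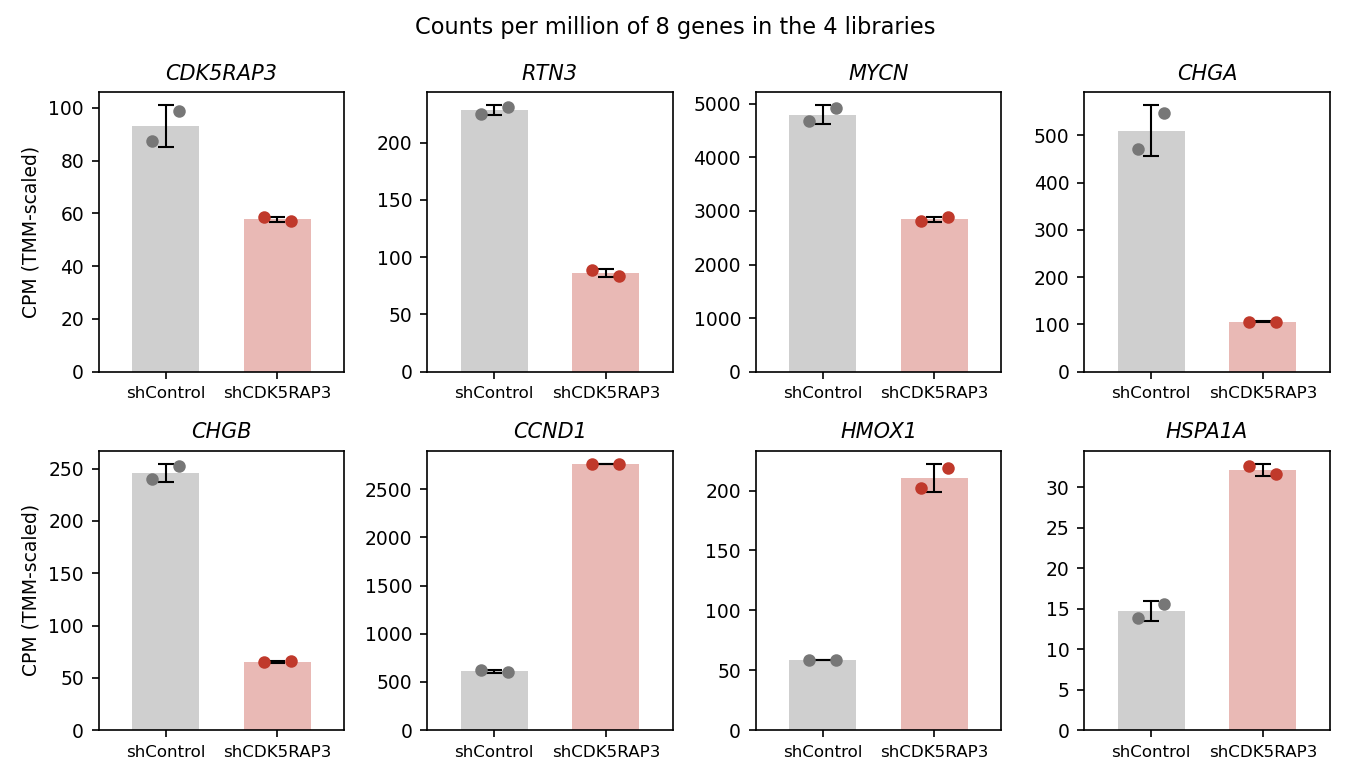
TMM-scaled CPM (vertical axis, starting at 0) of 8 genes in the shControl (grey) and shCDK5RAP3 (red) libraries, with points for the 2 libraries of each group, bars for the mean and error bars for the SD. The shCDK5RAP3 libraries lie below both controls for CDK5RAP3, RTN3, MYCN, CHGA and CHGB, and above both for CCND1, HMOX1 and HSPA1A.

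UFMylation attaches the small modifier UFM1 to proteins such as the ribosomal protein RPL26 at the ER. Of the 11 genes of this pathway that were tested, 3 rose, 2 fell and 6 did not pass, with the same 3 and 2 when p-values were adjusted over the list alone. UFM1 rose 1.51-fold, from 30.7 ± 2.01 to 46.3 ± 0.241 CPM (SD, n = 2 each; log2 change 0.60 ± 0.09 SE, edgeR adjusted p = 0.00064). ODR4 rose by 0.28 and RPL26 by 0.20 on the log2 scale. Besides CDK5RAP3, the protease gene UFSP2 fell, by 0.40. These 3 calls were lost without shCDK5RAP3 replicate 1 (edgeR adjusted p = 0.0596 for UFSP2, 0.0892 for ODR4, 0.119 for RPL26) and without shCDK5RAP3 replicate 2 (0.132, 0.217, 0.17), and those of ODR4 and RPL26 also without shControl replicate 1 (0.13, 0.0665). ODR4 did not pass with DESeq2 (0.0643) or by library size (0.0533) either. Among those that did not pass were the conjugating enzyme UFC1 (-0.12), the ligase UFL1 (0.13), its partner DDRGK1 (0.18), UFSP1 (-0.43) and SAYSD1 (-0.01). The list as a whole did not stand apart (camera adjusted p = 0.653), and its median of 0.13 and mean of -0.01 differ in sign.

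ER-phagy receptors are membrane or adaptor proteins that hand pieces of ER to autophagosomes. Of 12 tested, 4 fell, 2 rose and 6 did not pass; adjusted over the list alone, 5 fell and 2 rose. RTN3 (ENSG00000133318, chromosome 11, 63681446 to 63759891) went from 228 ± 4.35 to 86.1 ± 3.19 CPM (SD, n = 2 each; log2 change -1.41 ± 0.06 SE, edgeR adjusted p = 1.7e-06). ATL1 fell by 0.68, CALCOCO1 by 0.65 and RETREG3 by 0.27, and ATL2 and SEC24C rose by 0.44 and 0.26. The annotated 3′ UTRs of RTN3, ATL1 and ATL3 hold the 7-base word AACACCT. RETREG1 (FAM134B), with 27, 47, 19 and 11 counts, had a log2 change of -1.29 and an edgeR adjusted p of 0.0527. TEX264 (-0.37), CCPG1 (-0.13), SEC62 (-0.09), ATL3 (-0.05) and RETREG2 (0.13) did not pass either. The list did not pass the camera test (adjusted p = 0.257). RETREG3 and SEC24C lost their calls without shCDK5RAP3 replicate 1 (edgeR adjusted p = 0.066 and 0.127) and without shCDK5RAP3 replicate 2 (0.201 and 0.0689), RETREG3 also without shControl replicate 1 (0.0749). RETREG1 passed by library size (0.0497), with the robust fit (0.0475), summed by symbol (0.0414), with the GC content and length correction (0.0462) and without shControl replicate 1 (0.028). TEX264 passed without shControl replicate 1 (0.0278), and RETREG2 with the GC content and length correction (0.0411).

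The core autophagy list had 14 members that rose and 6 that fell of 37 (14 and 7 adjusted over the list alone), and its median of 0.10 and mean of -0.02 again differ in sign (camera adjusted p = 0.437). The falls included the PI3P effector WIPI1 (-1.62), the kinase ULK2 (-1.31) and the cargo receptors CALCOCO2 (-1.12) and TAX1BP1 (-1.02). ULK2 and TAX1BP1 hold the word ACACCTA in their 3′ UTRs. Named after their values were seen, the cargo receptor SQSTM1 (0.93), VMP1 (0.76) and the ULK2 paralog ULK1 (0.72) led the rises, as did ATP6V0D1 (0.70) and TFE3 (0.67) among lysosomal genes and DNAJB9 (0.56) and SYVN1 (0.53) among those of the ER. Lysosomal genes had 5 rises and 12 falls of 37 (7 and 13 adjusted over the list alone; camera adjusted p = 0.456), with CTSF (-1.43), LIPA (-1.36) and NAGLU (-1.21) lower. Of 29 ER chaperone and unfolded-protein-response genes, 6 rose and 10 fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.542). CRELD1 (-1.42), SEL1L (-0.81) and the lectin chaperone CANX (-0.74) were lower. XBP1 (log2 change -1.06, edgeR adjusted p = 0.016) varied between the shCDK5RAP3 libraries, with 1554 and 701 counts against 2191 and 2515, and DESeq2 did not call it (adjusted p = 0.153), nor did the robust edgeR fit (0.285). XBP1 holds AACACCT in its 3′ UTR, and its log2 change was -1.77 without shCDK5RAP3 replicate 1 and -0.58 without shCDK5RAP3 replicate 2.

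**Figure D2:**
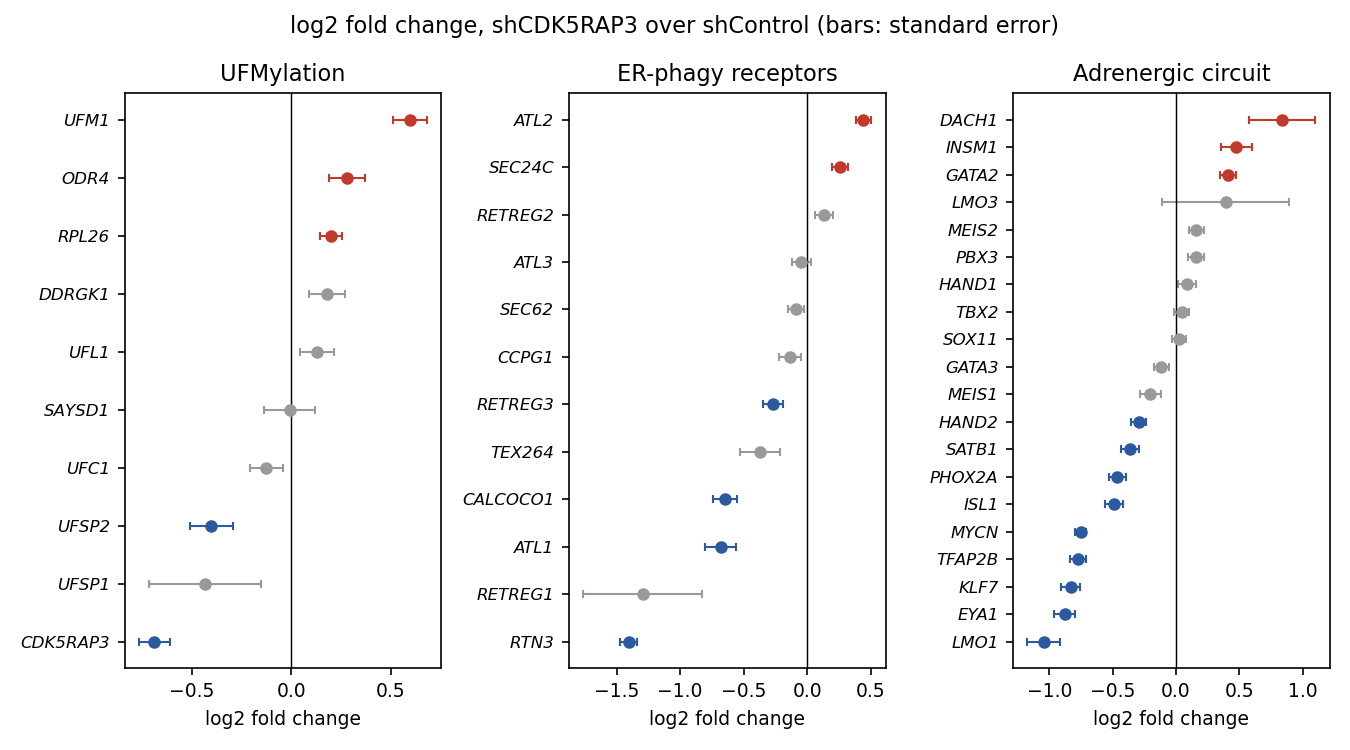
Log2 fold change of shCDK5RAP3 over shControl (horizontal axis; bars show the standard error) for members of the UFMylation, ER-phagy receptor and adrenergic circuit lists, with red for genes that rose, blue for genes that fell and grey for genes that did not pass an edgeR adjusted p of 0.05. RTN3 at -1.41 and LMO1 at -1.04 are the lowest points of their panels, and UFM1 at 0.60 is the highest of the UFMylation genes.

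The adrenergic circuit is the set of transcription factors that maintain the noradrenergic state of neuroblastoma. Of its 22 tested members 10 fell, 3 rose and 9 did not pass, and adjusted over the list alone 10 fell and 5 rose. MYCN (ENSG00000134323, chromosome 2, 15940564 to 15947007) fell from 4797 ± 175 to 2847 ± 47.8 CPM (SD, n = 2 each; log2 change -0.75 ± 0.05 SE, edgeR adjusted p = 6.74e-06). LMO1 (-1.04), EYA1 (-0.88), KLF7 (-0.83), TFAP2B (-0.77), ISL1 (-0.49), PHOX2A (-0.46), SATB1 (-0.36) and HAND2 (-0.29) also fell, KLF7 with the word AACACCT in its 3′ UTR. DACH1 (0.84), INSM1 (0.48) and GATA2 (0.41) rose. MEIS2 and PBX3 (0.16 each), MEIS1 (-0.20), GATA3 (-0.11), HAND1 (0.09), LMO3 (0.39), TBX2 (0.04) and SOX11 (0.03) did not pass. With members going both ways, the list did not pass as a set (camera adjusted p = 0.183). Without shCDK5RAP3 replicate 2 the calls of HAND2 (edgeR adjusted p = 0.063), INSM1 (0.0765), SATB1 (0.0913) and DACH1 (0.174) were lost, without shCDK5RAP3 replicate 1 those of HAND2 (0.0906) and INSM1 (0.081), and without shControl replicate 1 that of DACH1 (0.0923). DESeq2 did not call DACH1 (adjusted p = 0.0985). MEIS2 and PBX3 passed with upper-quartile factors (0.0324 and 0.0345) and with the GC content and length correction (0.0132 and 0.0343), MEIS2 also summed by symbol (0.0447), and MEIS1 without shControl replicate 2 (0.033). MYCN shares its locus with the antisense gene MYCNOS (-1.10), and the strand setting of the counting is not given in the sources used here.

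Genes of noradrenergic neuron function fell as a set. Of 35 tested, 24 fell, 5 rose and 6 did not pass, the same 24 and 5 adjusted over the list alone, with a median log2 change of -0.66 (camera adjusted p = 0.000333). This call was lost when the correlation was estimated (adjusted p = 0.517 with an estimated correlation). CHGA fell from 510 ± 53.8 to 105 ± 0.732 CPM and CHGB from 246 ± 8.49 to 65.5 ± 0.982 CPM (SD, n = 2 each; log2 changes -2.27 and -1.91, edgeR adjusted p = 4.69e-07 and 4.32e-07). The vesicular monoamine transporter SLC18A1 (-2.77) and the prohormone convertase PCSK1 (-2.65) had the steepest falls of the list, from 1.55 and 3.59 CPM, with SLC18A1 at -3.43 without shCDK5RAP3 replicate 2. Named after their values were seen, tyrosine hydroxylase TH (-1.07) and dopamine beta-hydroxylase DBH (-1.48), which make noradrenaline, fell as well. None of the 4 leading genes, nor MYCN, holds AACACCT or ACACCTA in its annotated 3′ UTR.

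Mesenchymal-state genes went both ways, with 7 rises and 10 falls of 23, the same counts adjusted over the list alone (camera adjusted p = 0.88), with a median of -0.19 and a mean of 0.09 that differ in sign. The YAP targets CCN2 (2.82) and CCN1 (1.79) and the AP-1 factor FOSL1 (2.45) rose, whereas AXL (-2.09) fell from 24 and 28 counts to 9 and 3, a call lost without shCDK5RAP3 replicate 2 (log2 change -1.50, edgeR adjusted p = 0.115) and without shControl replicate 2 (0.0885) and with DESeq2 (0.0583), and at -3.08 without shCDK5RAP3 replicate 1. Extracellular matrix and adhesion genes had 5 rises and 11 falls of 35, the same adjusted over the list alone (camera adjusted p = 0.473). The gelatinase MMP2 dropped to 7.58% of control, from 708 ± 25.1 to 53.7 ± 1.23 CPM (SD, n = 2 each; log2 change -3.72 ± 0.07 SE, edgeR adjusted p = 2.2e-08). TIMP3 (-1.99) and SERPINH1 (-1.11) were also lower. MMP2 holds ACACCTA and SERPINH1 AACACCT in the 3′ UTR.

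Markers of other cell types did not rise together. Fibroblast markers had 4 rises and 7 falls of 14 (4 and 9 adjusted over the list alone; camera adjusted p = 0.248), with TAGLN (2.13) and ACTA2 (2.06) higher and PDGFRB (-2.32) and DCN (-1.73) lower. Of 10 leukocyte, endothelial and epithelial markers 3 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.183): KRT19 (-2.07), EPCAM (-0.88) and CDH5, which had 17 and 11 counts against 0 and 0 and was at least 4.68-fold lower, taking 3 counts per library as the floor. KRT19 was at -2.82 without shCDK5RAP3 replicate 2, EPCAM lost its call without shCDK5RAP3 replicate 1 (edgeR adjusted p = 0.0961) and CDH5 lost its call without shCDK5RAP3 replicate 2 (0.05). Only 4 Schwann cell markers were expressed, too few for the set test, and S100B (-2.17) and PMP22 (-0.96) fell, both also adjusted over the list alone.

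Among stress-responsive genes more rose than fell. Of 20 heat-shock genes 18 rose, 0 fell and 2 did not pass, the same adjusted over the list alone, with a median of 0.68 (camera adjusted p = 1.63e-06; adjusted p = 0.517 with an estimated correlation). The small heat-shock protein HSPB8 (1.37) and the HSP70 cochaperone HSPH1 (1.14, from 70.5 ± 2.10 to 155 ± 4.89 CPM) led, followed by HSPA1A (1.12) and HSPA1B (0.97), near-identical copies whose values are uncertain. Of 24 immediate-early genes 17 rose and 1 fell, or 17 and 2 adjusted over the list alone (median 0.81; camera adjusted p = 2.35e-05; adjusted p = 0.517 with an estimated correlation). FOSL1 (2.45), MYC (2.32, at about 1 CPM), CCN1 (1.79) and ATF3 (1.63) led them, MYC with an edgeR adjusted p of 0.0517 without shCDK5RAP3 replicate 1. NRF2 targets of the antioxidant response had 12 rises and 1 fall of 24, or 15 and 1 adjusted over the list alone (camera adjusted p = 0.00054; adjusted p = 0.517 with an estimated correlation), including the cystine transporter SLC7A11 (2.16), OSGIN1 (2.10), the haem oxygenase HMOX1 (1.85) and AKR1C1 (0.95), which has close paralogs. The integrated stress response list had 16 rises and 8 falls of 32, or 16 and 9 adjusted over the list alone (camera adjusted p = 0.0348; adjusted p = 0.517 with an estimated correlation), with SLC7A11, GDF15 (2.16), ATF3 and DDIT3 (1.18) at its head. Its camera call was lost without shControl replicate 1 (0.0853), shControl replicate 2 (0.0562) or shCDK5RAP3 replicate 2 (0.1).

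**Figure D3:**
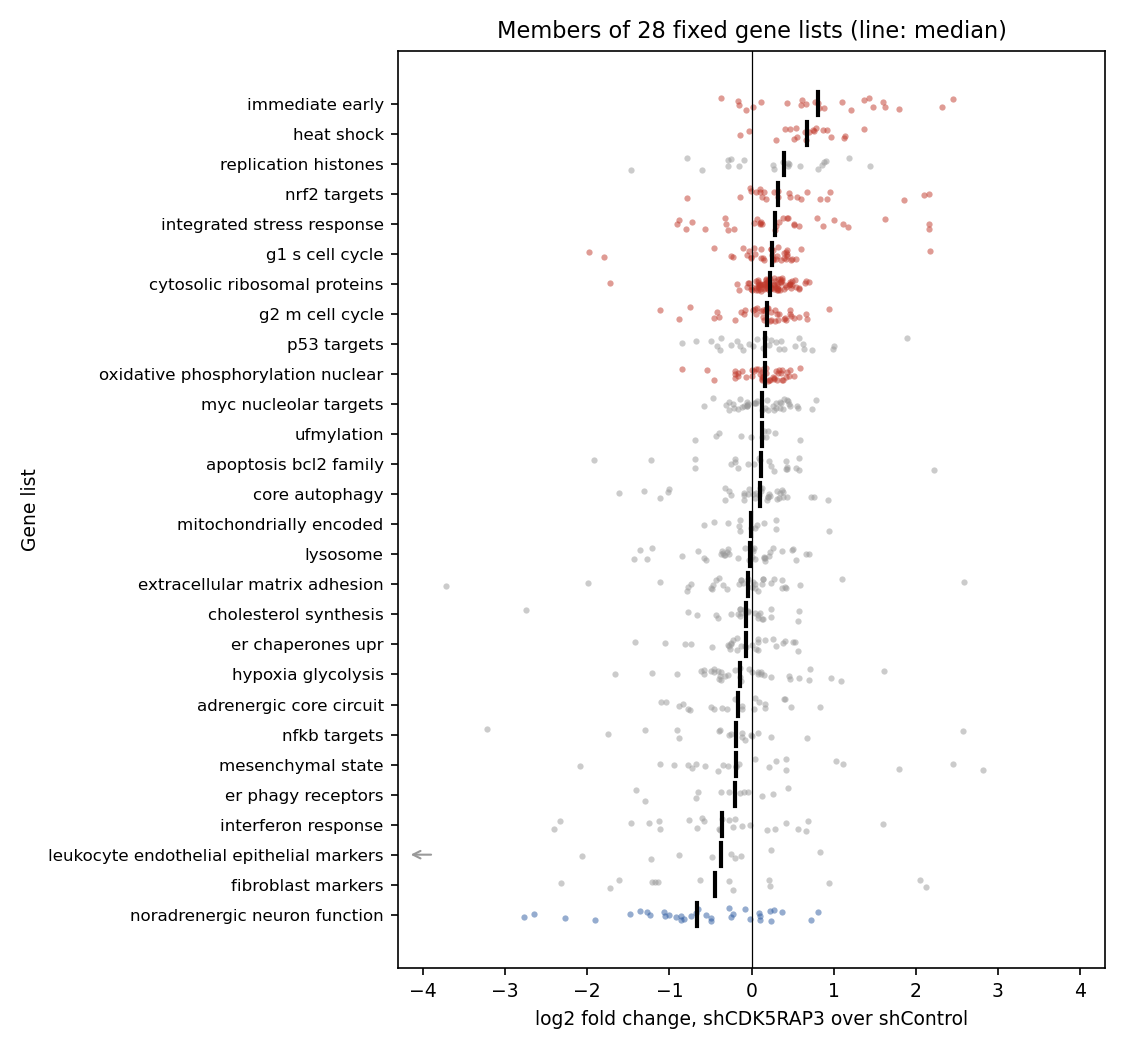
Log2 fold change of shCDK5RAP3 over shControl (horizontal axis) for each tested member of 28 gene lists (vertical axis), with a point per gene and a black line at the median; red and blue mark lists past a camera adjusted p of 0.05 upward and downward, and an arrow marks 1 gene beyond the axis. The noradrenergic neuron list has the lowest median, -0.66, and the immediate-early list the highest, 0.81.

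In both cell-cycle lists more genes rose than fell, by modest amounts, while single cyclins moved further. The G1/S list had 22 rises and 4 falls of 38, the same adjusted over the list alone (median 0.25; camera adjusted p = 0.00515; adjusted p = 0.517 with an estimated correlation). Cyclin D1 (CCND1) rose 4.51-fold, from 613 ± 15.7 to 2761 ± 3.12 CPM (SD, n = 2 each; log2 change 2.17 ± 0.05 SE, edgeR adjusted p = 1.12e-07). MCM5 rose by 0.60, while the E-type cyclins CCNE2 (-1.98) and CCNE1 (-1.79), which act at entry into S phase, fell. The G2/M list had 20 rises and 6 falls of 41, or 23 and 7 adjusted over the list alone (camera adjusted p = 0.0215; adjusted p = 0.517 with an estimated correlation), a call lost without shControl replicate 2 (0.0562) or shCDK5RAP3 replicate 2 (0.0564). CDC20 (0.94) rose, and HMMR (-1.11), ANLN (-0.89) and the proliferation marker MKI67 (-0.74) fell. HMMR holds AACACCT in its 3′ UTR, and MKI67 had an edgeR adjusted p of 0.0648 without shCDK5RAP3 replicate 2.

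Among ribosomal protein transcripts the rises were small. Of 79 tested 50 rose, 2 fell and 27 did not pass, or 53 and 3 adjusted over the list alone (median 0.23; camera adjusted p = 4.66e-06; adjusted p = 0.651 with an estimated correlation and 0.0927 with fry). RPL18 (0.70), RPL35 (0.66) and RPL13 (0.65) rose, but RPL37 fell to 30.3% of control (log2 change -1.72), and these genes have many processed pseudogenes of near-identical sequence. MYC-driven nucleolar genes had 17 rises and 5 falls of 41, or 19 and 5 adjusted over the list alone (camera adjusted p = 0.131), with TCOF1 (0.78), PPAN (0.74) and PES1 (0.57) higher and LDHA (-0.58) lower; this list passed without shCDK5RAP3 replicate 1 (0.0497). Nuclear genes of oxidative phosphorylation had 20 rises and 5 falls of 44, or 20 and 6 adjusted over the list alone (camera adjusted p = 0.0348; adjusted p = 0.728 with an estimated correlation), among them SDHD (0.59) and NDUFA9 (0.52) upward and NDUFB5 (-0.85) and ATP5MC1 (-0.54) downward. That camera call was lost without shControl replicate 1 (0.238) or shCDK5RAP3 replicate 2 (0.16), with fry (0.176) and without the genes whose 3′ UTR holds AACACCT or ACACCTA (0.126). The 13 mitochondrially encoded mRNAs split, with 4 rises and 5 falls (4 and 6 adjusted over the list alone; camera adjusted p = 0.88): MT-ND1 (0.94) and MT-ND5 (0.30) rose and MT-CO2 (-0.58) and MT-CO3 (-0.46) fell. ATP5MC1 and MT-ND5 lost their calls without shCDK5RAP3 replicate 1 (edgeR adjusted p = 0.0711 and 0.0713), and MT-ND5 also without shCDK5RAP3 replicate 2 (0.0538).

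The remaining lists did not pass the camera test. p53 targets had 9 rises and 4 falls of 29, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.248), with TNFRSF10B (1.90) and SESN2 (1.00) higher and BTG2 (-0.84) and TP53INP1 (-0.67) lower. BCL2-family genes had 9 rises and 4 falls of 23, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.437), with HRK (2.22) higher and BOK (-1.91), BCL2 (-1.23) and BID (-0.69) lower. HRK and BOK lost their calls without shCDK5RAP3 replicate 2 (edgeR adjusted p = 0.0584 and 0.0562), HRK was at 3.11 without shControl replicate 2, and BOK at -2.69 without shCDK5RAP3 replicate 1. TP53INP1, BOK and BCL2 hold AACACCT or ACACCTA in the 3′ UTR.

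NF-kB targets had 1 rise and 4 falls of 18, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.183): CXCL8 (2.57, from 5 and 0 counts to 17 and 14) rose and VCAM1 (-3.22, from 27 and 31 counts to 6 and 0), TNFAIP2 (-1.75) and RELB (-1.30) fell. The log2 change of CXCL8 was 1.6 without shControl replicate 2 and 6.97 without shControl replicate 1, and that of VCAM1 -2.23 without shCDK5RAP3 replicate 2 and -7.87 without shCDK5RAP3 replicate 1; the larger value of each sets counts against 0 and so has no upper bound. The CXCL8 call was lost with DESeq2 (adjusted p = 0.108), by library size (0.0503) and without shControl replicate 2 (edgeR adjusted p = 0.224), shCDK5RAP3 replicate 1 (0.236) or shCDK5RAP3 replicate 2 (0.195). Those of VCAM1 and RELB were lost without shCDK5RAP3 replicate 2 (0.0551 and 0.111), and that of RELB without shControl replicate 1 (0.0964) and with DESeq2 (0.0763). Interferon-response genes had 2 rises and 7 falls of 25, the same adjusted over the list alone (camera adjusted p = 0.248), with BST2 (-2.40), IFI35 (-2.33) and PARP14 (-1.47) lower and ISG15 (1.6) higher. BST2 was at -3.07 without shCDK5RAP3 replicate 2, IFI35 at -3.15 without shCDK5RAP3 replicate 1, and ISG15 lost its call without shCDK5RAP3 replicate 2 (0.125). PARP14 holds AACACCT in the 3′ UTR.

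Cholesterol synthesis had 4 rises and 5 falls of 25, the same adjusted over the list alone (camera adjusted p = 0.552), with STARD4 (-0.78) and TM7SF2 (-0.66) lower and SC5D (0.58) higher. TM7SF2 lost its call without shCDK5RAP3 replicate 1 (edgeR adjusted p = 0.0873). Hypoxia and glycolysis genes had 9 rises and 13 falls of 36, or 9 and 15 adjusted over the list alone (camera adjusted p = 0.437), with ANGPTL4 (1.61), SLC16A3 (1.09) and P4HA2 (0.97) higher and PDK1 (-1.21) lower. ANGPTL4 was at 2.38 without shControl replicate 1 and lost its call without shCDK5RAP3 replicate 1 (0.0829) or shCDK5RAP3 replicate 2 (0.1), and P4HA2 without shCDK5RAP3 replicate 2 (0.0728). Among 21 replication-dependent histone genes only H2BC8 (1.19) rose, and 0 passed adjusted over the list alone (camera adjusted p = 0.275); H2BC8 did not pass without shControl replicate 1 (0.152), shControl replicate 2 (0.125), shCDK5RAP3 replicate 1 (0.119) or shCDK5RAP3 replicate 2 (0.164), with DESeq2 (0.194) or with the GC content and length correction (0.0532). PDK1 holds ACACCTA in the 3′ UTR.

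Of the 12 largest rises among expressed genes 7 were products of the ribosomal RNA repeats, 1 of them the largest. MIR3648-1 (4.01) and MIR3648-2 (3.62) lie in the spacer of the precursor, and the 5.8S genes RNA5-8SN1 (3.25), RNA5-8SN4 (3.24), RNA5-8SN3 (3.21), 5_8S_rRNA (3.01) and RNA5-8SN2 (3.0) are near-identical copies, so the value of any 1 copy is uncertain. The neuronal pentraxin NPTX1 (3.96) rose 15.5-fold, from 1.26 ± 0.264 to 19.6 ± 0.14 CPM (SD, n = 2 each; edgeR adjusted p = 1.9e-06). EPPK1 (3.85), the chemokine CXCL12 (3.81), the metallothionein MT1E (3.67) and the checkpoint ligand gene CD274 (2.92) were the other protein-coding genes of this set, all with under 2 CPM in the control libraries. The largest falls after MMP2 were HSPB7 (-3.40), ARL2BP (-3.32), CAPN6 (-3.23), KIAA0040 (-3.04), CDK15 (-2.94), the neurotrophin receptor NGFR (-2.80), the neuronal microtubule protein DCX (-2.78), DAND5 (-2.77) and NAT1 (-2.76). ARL2BP, CAPN6 and CDK15 hold AACACCT or ACACCTA in the 3′ UTR. The readthrough gene ISY1-RAB43 had 92 and 182 counts against 0 and 0 and was at least 45.7-fold lower with 3 counts per library as the floor, an uncertain value because it shares exons with ISY1 and RAB43. PCDHGA9 (-2.81) rested on shControl replicate 2, with 23 and 252 counts against 19 and 20, and without that library its log2 change was -0.25 (edgeR adjusted p = 0.788); it did not pass without shCDK5RAP3 replicate 1 (0.197) or shCDK5RAP3 replicate 2 (0.255), with DESeq2 (0.11), with limma-trend (0.107) or with the robust edgeR fit (0.31). It was at -3.69 without shControl replicate 1. HSPB7 was at -4.02 without shCDK5RAP3 replicate 2, and KIAA0040 at -4.01 without shCDK5RAP3 replicate 1 and -2.45 without shCDK5RAP3 replicate 2.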

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

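The alternatives with GC content and length, annotated genes and 3′ UTR words were chosen after seeing the data. CDK5RAP3 kept its direction and side of the threshold in every alternative run, with log2 changes from -0.60 to -0.77. The count of genes changed, 7792, moved beyond 1.5 times only without a filter (4488, and 1310 changed at least 2-fold against 1972) and with single libraries left out (3752 to 7329, lowest without shCDK5RAP3 replicate 2; 1368 to 1923 changed at least 2-fold). It was 6697 with DESeq2, 7816 with limma-trend, 5235 at a threshold of 0.01, 8321 with the GC content and length correction and 6500 without genes holding AACACCT or ACACCTA. Equal replicate numbers do not pair these libraries by any label, and the deviations of the replicate 1 libraries correlated at 0.053 over all tested genes. That value takes in low-count genes, so it does not exclude an effect shared by replicate number among abundant ones. With the replicate block 9148 genes passed, 9147 with the GC correction too, and 8 lists, the integrated stress response (adjusted p = 0.0506) and the gene H2BC8 (0.0522) losing their calls and RETREG1 (0.0413), TEX264 (0.0199), MEIS1 (0.018), MEIS2 (0.0152) and PBX3 (0.0217) passing. Of the 9 lists past camera, 0 remained with an estimated correlation, 6 to 10 lists passed with 1 library left out, and fry called 20. Upper-quartile scaling put 51.2% of calls upward against 47.5% with TMM factors and 43.8% by library size. Over the named genes and their alternatives, 2336 values stayed, 100 lost their call, 18 gained one and 11 reversed. The reversals, each of a gene that did not pass, were SAYSD1 (0 with RLE, DESeq2; 0.02 with upper-quartile factors; 0.01 summed by symbol; -0.12 to 0.1 with 1 library left out, 0.04 without shCDK5RAP3 replicate 2), SOX11 (0 by library size), LMO3 (-0.18 to 1.25, -0.14 without shControl replicate 1), ATL3 (-0.1 to 0.01) and HAND1 (0 to 0.18), the last 3 with 1 library left out. The mitochondrial list turned with 1 library left out (adjusted p = 0.714 to 0.996, turned at 0.927 and 0.996), and the mesenchymal list with 1 library left out (0.719 to 0.996, turned at 0.996), with fry (0.101) and without the word-holding genes (0.86). The causes were not tested.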

Other observations

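The families of genes sharing a symbol stem, the markers of other cells, the batch, the classes of word match with their adjustment for UTR length, the chance rates of the target words and the neighbours of MYCN were all chosen for testing after the results were seen. Of 221 families with at least 10 tested members, 12 passed camera, and all 12 had an adjusted p of 0.901 with an estimated correlation. Of the ADAMTS extracellular proteases 12 fell and 1 rose among 18 tested (median log2 change -0.72; camera adjusted p = 0.0107; adjusted p = 0.901 with an estimated correlation). Tetraspanins fell too, with 12 falls and 0 rises of 18 (median -0.42; camera adjusted p = 0.0121; adjusted p = 0.901 with an estimated correlation), as did semaphorins, with 12 falls and 2 rises of 21 (camera adjusted p = 0.0415; adjusted p = 0.901 with an estimated correlation). The TIMM translocases of the mitochondrial inner membrane had 11 rises and 0 falls of 16 (median 0.41; camera adjusted p = 0.0107; adjusted p = 0.901 with an estimated correlation), and the MRPL mitochondrial ribosomal proteins 23 rises and 4 falls of 54 (median 0.24; camera adjusted p = 0.0107; adjusted p = 0.901 with an estimated correlation). The others were PRPF, SEC, MED and DDX (medians 0.41, 0.33, 0.30 and 0.28) and CDH, RGS and CD (medians -0.48, -0.51 and -0.37).

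All 8 tested 5.8S ribosomal RNA rows rose, by 3.0 to 3.25 on the log2 scale, and 18 identifiers that matched no table rose by over 3. Of 4 further RNAs without a poly(A) tail that were tested as a fixed list, RPPH1 (3.10) and SNORD3A (2.00) rose while RN7SL1 (-0.63) and RN7SL2 (-0.71) fell; SCARNA12 (2.08), named after its value was seen, rose. RPPH1 had an edgeR adjusted p of 0.0778 without shCDK5RAP3 replicate 2, and SNORD3A did not pass without any 1 of the libraries (0.0619 to 0.196) or with DESeq2 (0.0998). The replication-dependent histone mRNAs had a median of 0.39 with quartiles of -0.25 and 0.81. By RNA class, not fixed in advance, 12 mitochondrial tRNAs of 22 and 3 small nucleolar RNAs of 18 rose and 0 fell. Of 17 RNAs of the miscellaneous class, 2 rose and 5 fell. A less complete removal of RNAs without a poly(A) tail in the shCDK5RAP3 libraries was weighed by these values alone. It stayed undecided, since the RNAs went both ways.

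Transcripts with particular 7-base words in the 3′ UTR were lower in the shCDK5RAP3 libraries. Over 11661 protein-coding genes and 16226 words, AACACCT gave the lowest statistic, -14.6, and the overlapping ACACCTA -12.59, where 100 permutations reached no lower than -5.35. On the higher side GCACTTT (6.48) and ACGCCTG (5.24) passed the highest of the permutations, 5.09; they stood in 28.85% and 12.69% of the genes that rose and 25.22% and 10.3% of those that did not pass. The word AACACCT stood in the 3′ UTR of 17.91% of the genes that fell, 9.72% of those that did not pass and 6.29% of those that rose. The effect grew with the match: the mean log2 change was -0.02 for 7586 genes without ACACCT, -0.11 for 2249 with ACACCT alone, -0.27 for 526 with ACACCTA, -0.28 for 1036 with AACACCT, -0.45 for 256 with 1 copy of AACACCTA and -0.86 for 8 with more copies, and 23.4%, 30.3%, 43.2%, 42.9%, 52.7% and 75% of them fell. UTR length rose along these classes, from a median of 979 to 4509 bases; beyond UTR length and base content the shifts against genes without ACACCT were -0.09, -0.26, -0.28, -0.47 and -0.90 (SE 0.015, 0.027, 0.021, 0.038 and 0.21). Of the 1826 genes holding either 7-base word 44.5% fell, against 25% of the others. This is an excess of 356 genes or 10.9% of the 3267 falls among the 11661 genes (344 genes or 10.5% beyond UTR length and base content). The others include the 2249 genes with ACACCT alone, so this excess covers AACACCT and ACACCTA only. The share was larger among steep falls: of the 782 falls of at least 2-fold, 257 held AACACCT or ACACCTA, against 24.9% of all 3267. In all, 12 words lay below the lowest of the permutations. Among them CTTCTCC stood in 28.16% of the genes that fell, 18.79% of those that did not pass and 16.09% of those that rose. Among the genes picked by the naming rule 18 of 78 that were lower and 5 of 52 that were higher hold AACACCT or ACACCTA. Those 5 were CCN1, RPL13, NDUFA9, SLC16A3 and AKR1C1.

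Such a pattern is what pairing of a hairpin's guide strand at its seed, bases 2 to 8, would give, and a candidate explanation is the guide of the CDK5RAP3 hairpin itself. The target holds the match: 29 of 37 annotated CDK5RAP3 transcripts contain AACACCT, and 26 the 8-base AACACCTA; the latter lies in the coding part of exon 5 (GRCh38 chromosome 17, 7-base word at 47974436 to 47974442, within GTATGAGAAGGACAACACCTACT), and a further AACACCT without the 8-base word in that of exon 12 (47980768 to 47980774). Of 3333 tested genes with transcripts of like length, 21.7% hold the 7-base and 4.4% the 8-base word, so the match alone could be chance; a further word, CTTCTCC (-8.24), stands in 12 CDK5RAP3 transcripts, which met the bound written before the test, but the rate in those genes, 50%, was looked up afterwards and leaves open whether it marks another guide. The falls of RTN3, ATL1, ULK2, TAX1BP1, MMP2 and BCL2 may therefore be partly direct hairpin effects, while CHGA, CHGB and MYCN lack AACACCT and ACACCTA in the 3′ UTR. CTTCTCC, ACACCT alone and coding matches were not looked up in CHGA, CHGB and MYCN. Effects through other genes that hold a word were not tested, so a hairpin effect on these genes stays open. Without the word-holding genes 8 lists passed camera, not oxidative phosphorylation (adjusted p = 0.126), and with an estimated correlation 0 lists pass even with these genes.

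For the large number of changed genes beside a partial loss of CDK5RAP3 mRNA, the tables argue against GC content and transcript length, since 96.9% of the calls with both values stayed called in the same direction after correction. They also argue against copy-number differences between the populations as the source of most changes. The 20 Mb windows explained 2.07% of the variance of the called changes. That is above the 0.58% at most of 100 permutations, so differences of single segments or in part of the cells stay open. Seed matches could account for part of the falls (statistic -14.6), and the 2 weaker words on the higher side leave open whether a seed of the control hairpin has a part in the rises. A batch or culture that differed between the groups cannot be told apart from the hairpin, because 0 batches named in the labels hold libraries of both groups. An effect of CDK5RAP3 loss itself stays open and was not tested separately.

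For the lower MYCN and noradrenergic transcripts, a smaller share of neuroblastoma cells among other cells was set against 28 markers of other cell types. Their median log2 change was -0.38, where such a mixture would raise them. But 4 rose and 12 fell, and their mean log2 CPM reached 8.06 in this cell line. They may thus report the tumour cells themselves, so the median cannot decide the question. Fewer copies of the MYCN region stay open. The median over the 15 other tested genes within 2 Mb was -0.54, below the bound of -0.38 written before the test, but 4 of them fell and 3 rose. The falls, MYCNOS (-1.10), ENSG00000236989 (-2.04), ENSG00000228876 (-2.5) and ENSG00000232444 (-1.73), start at 15921037 to 16316324, close to MYCN at 15940564. Of the rises, the pseudogene ENSG00000271315 (2.06) starts among them, at 16149251, and VSNL1 (1.8) and GEN1 (0.32) farther away, at 17539126 and 17753858. The nearest expressed coding genes, DDX1 (0.04, start 15591178) and NBAS (-0.12, start 15166909), did not pass. That pair was looked at only after the median was known, and the borders of the amplified segment are not known here. The fall of MYCN with LMO1, CHGA and CHGB could reflect a shift of the noradrenergic state, a hypothesis that was not tested. The -0.54 of the region bears directly only on the copies of MYCN, since LMO1, CHGA and CHGB lie on other chromosomes.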
